A study of Mus musculus with 81 samples.

How the data were processed

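Chromatin accessibility was measured in 81 mouse samples, which the labels place in 27 groups of 3. Per the submitters' processing notes, reads were processed with bcl2fastq 2.19.1, cutadapt 2.2.0, Bowtie2 2.2.5, SAMtools 1.4.1, MACS2 2.2.0 and bedtools 2.26.0 on the build mm10, with no parameters stated. Whether reads were shifted for the transposase cut, and which tool counted reads, is not given in the sources used here.

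The deposited peak lists hold a position and the peak caller's score for each peak, with a lowest score of 30 in every list but that of Q2 (32). The scores are the authors' and were used to rank or filter peaks within a list. Median scores are also given to describe some lists. There were 25 lists of 1 per group and 6 lists of 1 per sample, the latter for the aphidicolin experiment. Per the peak names, lists of the reprogramming course were called on merged replicates, and lists of the sorted fractions are consensus lists whose names and scores come from 1 library each. Pooling in the embryonic stem cell course is not given in the sources used here. The bulk list of the nascent arm at each reprogramming time was assigned by its name and by elimination from the list of the mature arm.

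The authors also deposited raw read counts over 139000 regions for the 6 libraries of the aphidicolin experiment. Its columns name the group and a number from 1 to 3 that no source ties to a sample, so the libraries are called a, b and c within each group, in the order of that number. The regions are those with a peak in all 3 aphidicolin lists or in all 3 untreated lists: 36320 met only the first condition and 2012 only the second. Library totals were 41183769 to 49440524 counts untreated and 55158844 to 78677381 with aphidicolin. Every pair of libraries differed by more than sampling noise (chi-square per degree of freedom 1.88 or more), so each counted as a sample. The labels do not say whether replicates came from separate cultures, and p-values measure only the spread between these samples, which may be technical.

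Counts were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM normalization, filterByExpr defaults) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The test was two-sided. After filtering, 138996 regions remained. Counts were also summed over the regions nearest to each gene (end within 50 kb) and tested for 17592 genes, a unit added after the count table was seen. The 16 gene lists, fixed before the data were examined, hold 277 genes, of which 274 were found in the gene table: naive pluripotency, general pluripotency, formative and EpiLC, germ layer and primitive streak, fibroblast, AP-1 and immediate early, epithelial, p53 and replication stress, S phase, mitosis, senescence and inflammation, ubiquitous promoters, imprinted, and markers of macrophage and blood, endothelial, and muscle and neural cells. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry. Region classes from the time course lists were added as sets after the count table was seen.

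Gene positions came from a table of 21883 protein-coding genes of the assembly GRCm38.p6, which shares its coordinates with mm10. It holds no strand, so a peak near a gene end lies within 1 kb of either end of a gene model, in place of the annotated start named in the design. A locus is the gene with 10 kb on each side. With no sequence at hand, motif tests and GC corrections were not run. Regions beside Pou5f1, Sox2, Klf4 and Myc can share reads with the inducible cDNA cassette, and those beside histone, interferon and actin genes with near-identical copies.

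Peaks were shared when they overlapped by at least 1 bp. Shares have Wilson 95% intervals, and odds ratios have 95% intervals over regions. Both cover counting error only, because 1 list per group leaves no spread between replicates. The set of regions open to gain was every region of the merged early lists outside the first bulk list. A narrower set, regions of the early bulk list only, was run first by mistake and its values were seen. It is kept as an alternative. List loci were set against 10000 random gene lists of the same size matched on peak number, as a description of these lists. In all, 16 lists in 10 list pairs were computed. A planned stratification by the strength of the later peak used the score of the first peak for loss and the region width for gain, because a lost region has no later score. Numbers of peaks per library were compared with two-sided exact permutation tests, which cannot go below 0.1 for 3 against 3.

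The genes named in the text follow a rule fixed before the data were examined. For aphidicolin it takes the 10 regions with the largest fold in each direction among those past the threshold, above the median log2 CPM and with groups that did not overlap, and up to 4 genes per list by the smallest p of a region. For the peak lists it takes 19 set genes and, per list, up to 4 genes in alphabetical order with a gene-end peak in either the first or the last list and not in the other. Gene-level examples in the aphidicolin lists were chosen after their values were seen.

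Alternatives covered normalization (DESeq2 1.42.0 size factors, library totals), the DESeq2 Wald test, filters, a tested fold of 1.5, leaving out each library, overlap, score, list length and peak width. Offsets that follow region strength (loess) and a restriction to the 100668 regions with a peak in all 6 lists were added after the data were seen. The count scripts were tested on simulated data with 50 features at each fold: 6% of regions at the smallest simulated fold, 56% at 1.5, 96% at 2 and 100% at 3 were recovered, against 70%, 96%, 100% and 100% of genes, with 8 unchanged features called in each. With so few changed features the adjusted threshold is stricter than in the real data. These rates therefore do not give the sensitivity of the real test. The overlap code gave 0 disagreements over 400 simulated intervals, and 5.2% of random lists lay beyond the central 95%. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.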

Results

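ATAC-seq reads open chromatin through the sites a transposase can reach, and repli-ATAC-seq restricts it to newly copied DNA captured through the nucleotide analogue EdU. Cells took up 20 µM EdU for 10 min and were either collected at once (nascent chromatin) or 2 h after labelling, following a chase in 10 µM thymidine (mature chromatin). DNA left unbound by the capture gave the bulk signal. Mouse embryonic stem (ES) cells were followed at 0h, 9h and 48h of conversion to epiblast-like cells (EpiLC). Mouse embryonic fibroblasts (MEF) carrying the inducible reprogramming factors OKSM were followed at 6h, 12h and 36h of 2 µg/mL doxycycline, with a bulk list for each capture arm, and at 60h in the sorted fractions Q1 to Q4 of a dye that cells dilute as they divide. The labels do not say which fraction was brightest. In a further experiment aphidicolin, an inhibitor of replicative DNA polymerases, was added at 5 µg/mL 4 h after induction for 10 h, with untreated MEF harvested at the same time. The 81 samples form 27 groups of 3. Bulk lists held 137173 to 203188 peaks, mature lists 14281 to 94946, nascent lists 3222 to 27693 and the sorted fractions 57762 to 73518. Coordinates are those of mm10.

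The aphidicolin experiment asks what becomes of accessibility in reprogramming cells when DNA replication is blocked. Largest changes are given among 27313 regions that were called, lay above the median log2 CPM and had groups that did not overlap. The strongest losses among them included regions at Actb, H2ac19, Actg1 and Zyx. A region 363 bp from the end of Actb (chromosome 5, 142902029 to 142902752), which encodes cytoplasmic actin, went from 4.87 ± 0.15 to 3.18 ± 0.17 log2 CPM (SD, n = 3), a log2 fold change of -1.68 ± 0.10 (SE, adjusted p = 2.6e-08). A region 48 bp from H2ac19 (chromosome 3, 96239363 to 96239731), a histone gene, changed by -1.68, and regions beside Actg1 by -1.44 and -1.23. A region 811 bp from an end of Zyx (chromosome 6, 42361024 to 42361838), which encodes a focal adhesion protein, changed by -1.38. One 964 bp from an end of Rpl35 changed by -1.17. Ciao3 (-1.32), Ifna13 (-1.30 and -1.27) and Prss12 (-1.18) complete the 10 largest losses among those 27313 regions. Reads at H2ac19, Ifna13 and the actin genes can be shared with near-identical copies, and these values are uncertain.

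Among the same 27313 regions, the 10 largest gains lay away from gene ends. They were nearest to Plppr4 (chromosome 3, 117310785 to 117311198, log2 fold change 1.38 ± 0.15, SE), Zeb2, Fat4 (1.21, inside a gene model), Gli3, Gata3 (1.18), Ranbp3l (1.17), 1700019D03Rik (1.17), Nyap2 (1.16), Fgf10 (1.15) and 2210010C04Rik (1.15). The regions named for Zeb2 and Gata3 lay 1535215 and 1086175 bp from those genes, so the names give position only. Of 138996 regions tested by edgeR's quasi-likelihood test, 25951 were higher and 25641 lower. With library totals in place of TMM the split was 43759 higher and 11504 lower (79.2% against 50.3% higher), and the median of all regions moved to 0.18, so all changes are relative to the bulk of regions. Most folds were small: 464 regions rose and 102 fell when a fold of 1.5 was tested. The number of called regions, 51592, was 33252 without aphidicolin library b, 31843 with offsets that follow region strength and 33626 over regions with a peak in all 6 lists.

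Regions within 50 kb of genes of 6 of the 16 lists fell as sets (camera, Benjamini-Hochberg over 16 lists, 3 libraries per group). The ubiquitous promoter list led (adjusted p = 1.9e-10), followed by AP-1 and immediate early genes (6.6e-07), mitosis (1.6e-05), fibroblast (0.00075), senescence and inflammation (0.0017) and S phase (0.0122). For regions within 50 kb, the ubiquitous, fibroblast, mitosis and senescence calls held with an estimated correlation. Over regions within 1 kb of a gene end 9 lists were called, but with an estimated correlation none was (adjusted p = 0.240, 0.177, 0.247 and 0.140 for those lists). AP-1 was lost (adjusted p = 0.135 with an estimated correlation), as was S phase (adjusted p = 0.328 with an estimated correlation), and S phase was lost with strength-dependent offsets too (adjusted p = 0.844). The second test, fry, which asks only whether a list moves on balance one way, also called the epithelial (adjusted p = 0.0422) and p53 lists (0.0436) as lower.

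Of 17592 genes tested on summed counts by edgeR, 4503 rose and 4579 fell (49.6% of called genes higher, 63.8% with library totals). In this unit, 12 of 16 AP-1 and immediate early genes fell and 0 rose (8 and 2 with strength-dependent offsets). The exceptions were Jun, Batf, Egr2 and Dusp6. Fosl2, an AP-1 subunit, changed by -0.35 ± 0.03 (SE) and Dusp1, a phosphatase gene induced by stress, by -0.25 ± 0.03. In the mitosis list 11 of 17 fell and 0 rose, with Ccna2, the gene of cyclin A2, at -0.40, Cdc20 at -0.34 and Cenpf at -0.28. Of 20 ubiquitous genes 13 fell and 1 rose, among them Rpl3 (-0.63), Actb (-0.49), Pgk1 (-0.47) and Gapdh (-0.37). Psma1 rose (0.16). Of 27 S phase genes 12 fell and 4 rose: Pold1 changed by -0.28 and Slbp by -0.27, while Mcm5 (0.14), Mcm6, Mcm7 and Pole rose, the last pair not called with strength-dependent offsets. The fibroblast list moved both ways, with 13 of 32 lower, including the collagen gene Col6a1 (-0.27) and Vim (-0.30), and 6 higher (11 and 9 with strength-dependent offsets), including Lum (0.70), Fap (0.68) and Col3a1 (0.39). Adjusted over the list alone, the counts were 13 lower and 1 higher for AP-1, 7 higher for fibroblast, and the same as over all genes for mitosis, ubiquitous and S phase genes.

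In the germ layer and primitive streak list 7 of 13 rose and 0 fell (6 and 1 with strength-dependent offsets), with Sox17 at 0.52 (not called with strength-dependent offsets), Pax6 at 0.39, Gata4 at 0.38 and Foxa2 at 0.34; its regions as a set did not pass the test (adjusted p = 0.405). Of 17 formative and EpiLC genes 6 rose, including Foxd3 (0.53), Otx2 (0.44) and Fgf5 (0.33), and 3 fell, Etv4, Etv5 and Tcf15. The naive pluripotency list split 7 and 7 of 17. Tcl1 (0.65, not called with strength-dependent offsets), Zfp42 (0.39) and Nr5a2 (0.36) rose, and Pou5f1 (-0.47), Sox2 (-0.46), Klf2 (-0.25) and Klf4 (-0.24) fell. Reads over Pou5f1, Sox2 and Klf4 can come from the reprogramming cassette, which makes those values uncertain. Over regions within 50 kb the naive, formative and macrophage lists had medians just above 0 (0.01, 0.02 and 0.00) where camera's direction was down, without passing. Within 1 kb of a gene end the naive list was called lower (adjusted p = 2.4e-05, median -0.30), but not with an estimated correlation (0.319). In the other lists rises and falls were 3 and 1 of 14 (general pluripotency), 5 and 4 of 18 (epithelial), 5 and 5 of 24 (p53 and replication stress, 8 and 3 with strength-dependent offsets), 2 and 3 of 14 (senescence and inflammation) and 2 and 0 of 9 (imprinted). Adjusted over the list alone 1 senescence gene and 1 imprinted gene rose, and the general pluripotency, epithelial, p53, naive, formative and germ layer counts stayed as given.

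Markers of cell types that a fibroblast culture could hold were called about as often as all genes (9082 of 17592). Of 8 endothelial genes 4 rose (5 adjusted over the list alone) and 1 fell, of 11 muscle and neural genes 5 rose and 1 fell (4 and 3 with strength-dependent offsets), and of 8 macrophage and blood genes 2 rose and 2 fell (1 and 3 with those offsets), the latter lists unchanged when adjusted over the list alone. Emcn (0.39) and Tek (0.26) were among the endothelial rises, Myod1 (0.61) among the muscle ones, and Cd68 (-0.42) fell. None of these 3 lists passed as a set of regions within 50 kb (adjusted p = 0.897, 0.549 and 0.405). Within 1 kb of a gene end the macrophage list was called lower (adjusted p = 0.0206), but not with an estimated correlation (0.240).

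**Figure D1:**
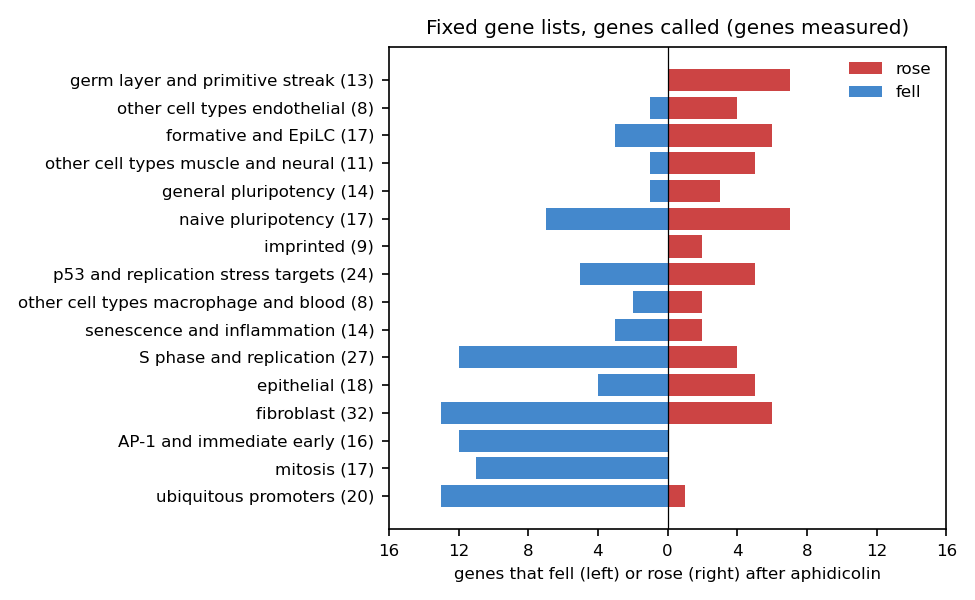
Bars give, for each fixed gene list, the number of genes that rose (right) or fell (left) after aphidicolin in the edgeR test on counts summed per gene (adjusted p below 0.05, 3 libraries per group), with genes measured in brackets. The AP-1 and mitosis lists hold 12 and 11 genes that fell and 0 that rose; the germ layer list holds 7 that rose and 0 that fell.

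Single regions of list genes spanned a wider range. Phlda3, a p53 target, held a region at -1.04 and Thbs1 one at -1.02, beside falls at Eef1a1 (-1.10), Col1a1 (-0.87, the locus that carries the reprogramming cassette), Jun (-0.72) and Sox2 (-0.77). A region nearest to Map2, a neuronal gene, changed by 1.18, one nearest to Igf2 by 1.12, one nearest to Esrp1 by 1.01 and one nearest to Atf3 by 0.89.

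Fold change followed region strength. The median log2 fold change was 0.39 in the weakest decile of regions and -0.32 in the strongest, where 54.9% of regions lay within 1 kb of a gene end. Regions within 1 kb of gene ends included 854 higher and 8107 lower, and regions over 10 kb away 21560 higher and 10770 lower. Regions that were bulk peaks at 6h and gone at 36h of reprogramming rose as a class (4716 higher and 429 lower of 12882, camera adjusted p = 1.1e-11, 0.0233 with an estimated correlation). With strength-dependent offsets 1958 were higher and 837 lower, and the median went from 0.33 to 0.09 (adjusted p = 0.0218). Of the 139000 regions, 36320 were included through the aphidicolin lists alone and 2012 through the untreated lists alone. This favours weak regions that are higher after aphidicolin. Neither the deciles nor this class were examined over regions with a peak in all 6 lists, so the part of these rises due to selection is not known. Regions gained by 36h at ES cell peaks held 615 higher and 614 lower of 3680 and did not pass (adjusted p = 0.738). With strength-dependent offsets they were lower (223 higher, 944 lower, adjusted p = 6.9e-06).

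**Figure D2:**
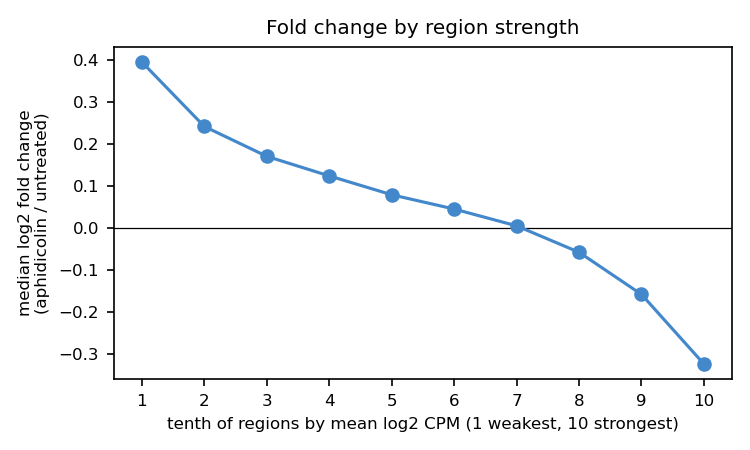
Points give the median log2 fold change (aphidicolin over untreated, TMM-normalized, 3 libraries per group) in deciles of the 138996 tested regions ordered by mean log2 CPM. The medians go from 0.39 in the weakest decile to -0.32 in the strongest.

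Aphidicolin libraries also gave more peaks. Untreated samples had 124481 ± 6659 peaks and aphidicolin samples 156855 ± 7931 (SD, n = 3 each), without overlap between the groups (exact permutation test, p = 0.1, the smallest possible). The share of peaks within 1 kb of a gene end was 14.1% ± 0.34 untreated and 11.8% ± 0.40 with aphidicolin (exact permutation p = 0.1, n = 3 each). The aphidicolin libraries were also the deeper ones, with 55158844 to 78677381 counts in the table against 41183769 to 49440524.

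Nascent, mature and bulk lists address how accessibility returns behind the replication fork. Nascent peaks were found mostly at strong bulk sites, and a larger share of them than of bulk peaks lay near gene ends. Nascent lists were far shorter, and a short list holds mainly strong peaks, which lie more often at gene ends. Part of this may therefore reflect detection. At 0h, 98.6% of nascent peaks in ES cells overlapped a bulk peak (Wilson 95% interval 98.4 to 98.8%) and 96.6% a mature peak, while 12.2% of bulk peaks had a nascent peak and 42.4% a mature one. Within 1 kb of gene ends lay 50.6% of nascent, 21.6% of mature and 12.9% of bulk peaks. In MEF at 12h these shares were 45.5%, 20.9% and 10.2%. At 6h of reprogramming 1.72% of bulk peaks had a nascent peak and 7.92% a mature one, against 10.3% and 32.1% at 12h. The 6h nascent and mature lists were weak, with 3222 and 14281 peaks and median scores of 65 and 80. At 12h they held 20968 and 62704 peaks, with medians of 129 and 188. Library yield and depth were not tested, so the lower shares at 6h do not by themselves show slower recovery.

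Among the strongest decile of bulk peaks at 0h, 73.5% had a nascent peak and 99.5% a mature one. Peaks of that decile at gene ends were found in nascent chromatin in 93.8% of cases and those elsewhere in 57.0%. At 12h of reprogramming the values were 91.5% and 51.6%. At single loci, Pou5f1, the gene of OCT4, held 4 nascent, 6 mature and 7 bulk peaks in ES cells at 0h, and Esrrb, a naive pluripotency regulator, 8, 23 and 45. Pooled over times, the gene-end share was 34.8 points higher in nascent than in bulk lists of the ES cell course and 40.7 points in reprogramming. With all lists brought to equal length by score the gaps were 7.94 and 12.3 points, so much of each gap went with list length.

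**Figure D3:**
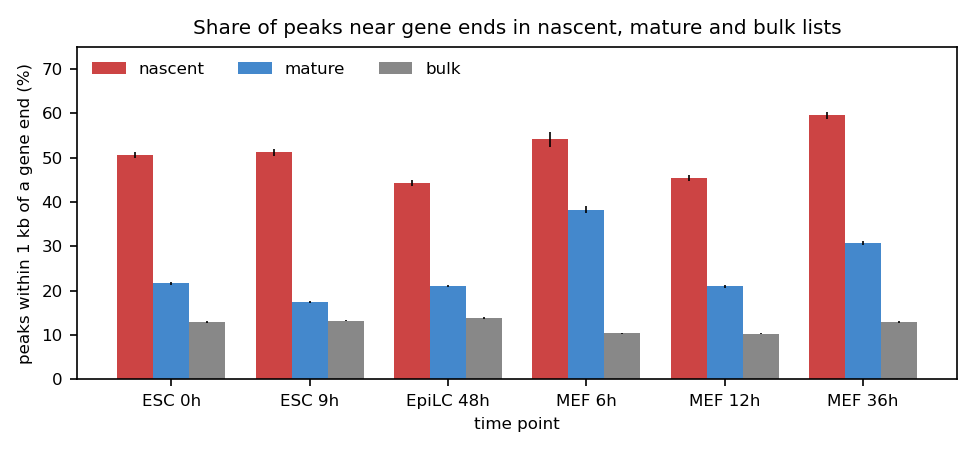
Bars give the percentage of peaks within 1 kb of a protein-coding gene end for nascent, mature and bulk lists at each time, 1 list per bar, with Wilson 95% intervals that cover counting error only. Nascent shares run from 44.3 to 59.6% and bulk shares from 10.2 to 13.8%.

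The change of bulk peaks over time describes the fate transitions themselves. Between 0h and 48h, ES cells lost peaks at naive pluripotency loci and gained them at formative ones. Peaks at the 18 naive loci went from 206 to 152, with fewer at 12 genes and more at 5, a median change at percentile 0.94 of random gene lists. Formative loci went from 154 to 186, more at 10 of 17 genes and fewer at 5 (percentile 99.99). Tfcp2l1 went from 17 to 18 at 9h and 7 at 48h, Zfp42 from 10 to 14 and 4, and Esrrb from 45 to 43 and 35. Dnmt3b, a de novo DNA methyltransferase gene, went from 7 to 9 and 14, Fgf5 from 3 to 5 and 7, Pou3f1 from 3 to 5 and 6, and Pou5f1 from 7 to 10 and 12.

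Esrrb, Nr5a2, Pdgfra, S100a4 and Mmp3 had a gene-end peak at 0h and none at 48h, and Sall2, Crb3, Rab25, Col6a1, Dcn, Snrpn, Emcn, Csf1r, Tyrobp and Myf5 gained one. Otx2 went from 10 to 8 peaks, Nanog from 6 to 8, Sox2 from 4 to 7 and Klf4 from 5 to 4. Mitosis loci went from 104 to 86 (percentile 0.025) and endothelial loci from 61 to 64 (percentile 98.8). In all, 38.9% of 0h bulk peaks had no 48h peak (95% interval 38.7 to 39.1%) and 34.9% of 48h peaks had no 0h peak. Peaks kept at both times lay at gene ends in 18.3% of cases, lost ones in 4.24% and gained ones in 5.39%. There is 1 list per time, so none of these changes was tested against replicates.

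In reprogramming MEF the 32 fibroblast loci held 456 bulk peaks at 6h, 555 at 12h (percentile 99.9) and 342 at 36h (percentile 11.9), with fewer at 21 genes and more at 5 by 36h. The whole lists held 177275, 199056 and 137173 peaks, so the 36h value lay near that of random lists. These lists are of the nascent arm. Those of the mature arm held 203188, 179656 and 142681 peaks, and their step from 6h to 12h was not set against random lists. Macrophage and blood loci went from 46 to 31 between 6h and 36h (percentile 6.84), endothelial loci from 88 to 69 (percentile 20.8) and mitosis loci from 79 to 80 (percentile 99.3). In the mature arm the 6h to 36h percentiles were 8.28 for fibroblast, 2.82 for macrophage and blood, 71.35 for endothelial and 100 for mitosis loci. Col1a1 held 10, 16 and 12 peaks and Snai2, a mesenchymal regulator, 3, 4 and 2. Runx1, Fap, Batf, Dnmt3l, Sall4, Gata4, Csf1r, Mmp13 and Mmp3 had a gene-end peak at 6h and none at 36h, and L1td1, Msgn1, Myog and Cdkn1a gained one, in the bulk lists of both arms. In the nascent arm alone Cldn6, Tie1 and Sox10 lost one and Sox17 gained one, and in the mature arm alone Krt18, Foxa2, Pax6, Igf2 and Lyz2 lost one and Lin28a, Otx2, Prdm14 and Ywhaz gained one. Naive loci held 77 peaks at 6h, 92 at 12h and 77 at 36h. Of the set genes, Zfp42 had 0, 1 and 0 peaks, Esrrb 13, 12 and 10, Nanog 2 at every time, Cdh1 13, 17 and 14, and Cdkn1a 3, 4 and 6.

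From 6h to 36h, 38.5% of bulk peaks were lost, and 20.6% of 36h peaks were gained. Gained peaks had an ES cell peak in 35.0% of cases (34.5 to 35.6%) and lost peaks in 8.21% (8.01 to 8.42%). In the bulk lists of the mature arm 12.6% of 36h peaks were gained, and at equal list lengths the lost and gained shares were 30.5% and 30.2%.

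The series title asks whether accessibility after replication foretells a fate change. Peaks with mature chromatin signal were more often kept. In ES cells, 0h bulk peaks with a 9h mature peak were absent at 48h in 20.7% of cases, and those without in 60.4% (odds ratio 0.171, 95% interval 0.167 to 0.175). In reprogramming, 6h bulk peaks with a 6h or 12h mature peak were absent at 36h in 2.02% of cases and those without in 57.7% (odds ratio 0.0151). Over only those peaks kept in the 9h or 12h bulk list, the odds ratio was 0.312 in ES cells and 0.0198 in reprogramming. Within 20 strata of the score of that bulk list, over the same kept peaks, it was 0.933 and 0.0900.

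For gained regions the direction differed between courses and settings. By construction, regions of the ES cell set without replicated signal were nearly all 9h bulk peaks, while those with it could lie outside the bulk lists. Of 9h mature peaks outside the 0h and 9h bulk lists, 18.9% were 48h bulk peaks. Outside the 0h list, regions with 9h nascent or mature signal were 48h bulk peaks in 34.1% of cases and those without in 41.2%. The odds ratio was 0.740 (0.707 to 0.775). At equal list lengths the ratio was 1.14, and over regions of the 9h bulk list, where both groups are bulk peaks, it was 1.01. Shortening to equal lengths also cuts the first bulk list, so weaker peaks of that list then count as outside it. The score filter cuts that list too. Values at equal lengths are therefore not ratios of gain alone. In reprogramming the regions with signal went from 2980 to 21009 in this way. Outside the 6h list, regions with early replicated signal were 36h bulk peaks in 69.8% of cases and others in 42.5% (odds ratio 3.12, 2.88 to 3.39). But the ratio was 0.750 with bulk lists of the mature arm, 0.695 at equal list lengths, 1.13 within strata of region width and 1.32 with peaks shortened to 200 bp. With higher-scoring peaks it was 8.53. Over regions of the 12h bulk list it was 13.1, and 9.59 within deciles of the 12h bulk score. For peaks of Q1 to Q4 at 60h the main ratio was 2.99, 3.34, 3.02 and 3.40, and at equal list lengths 0.974, 0.984, 0.906 and 0.686. These ratios were 1.07 to 1.33 with the mature arm, 1.39 to 1.53 within strata of width, 3.90 to 9.52 with peaks shortened to 200 bp and 4.80 to 5.22 with higher-scoring peaks. Over regions of the 12h bulk list they were 5.10 to 5.60, and 2.63 to 3.50 within deciles of the 12h bulk score. Of ES cell peaks outside the 6h bulk list, 0.477% had a 12h mature peak and 7.52% a 12h bulk peak.

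The sorted fractions ask how division relates to reprogramming. ES cell sites were most frequent in Q1 and least in Q4. Peaks at an ES cell site with no 6h MEF bulk peak made up 3.40% of Q1 (3.27 to 3.53%), 2.70% of Q2, 2.79% of Q3 and 0.989% of Q4 (0.911 to 1.07%), a ratio of 3.44 between Q1 and Q4. At equal list lengths the ratio was 2.04, and with peaks shortened to 200 bp 1.37. Q4 was also the weakest list: its median score was 170, against 356, 578 and 383 in Q1 to Q3. It covered 18.6 Mb, against 26.5, 25.2 and 28.9. Weak sites can drop out of a weaker list first, so list quality cannot be told apart from the fraction itself. The random lists used below were matched on peak number and not on score. Naive pluripotency loci held 48 peaks in Q1 and 22 in Q4, fewer at 14 of 15 genes and more at 0 (percentile 0.015 of random lists). Germ layer loci held 25 and 12 (percentile 0.58), and formative loci 61 and 40 (percentile 4.41).

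Esrrb held 4, 5, 4 and 2 peaks in Q1 to Q4, Tfcp2l1 5, 5, 5 and 2, Sox2 3, 2, 1 and 1, and Zfp42 and Otx2 0 in each. Cdh1, the gene of the epithelial cadherin, had a gene-end peak in Q1 and none in Q4, as had Epcam, Esrp1, Grhl2, Eomes, Gsc, Mixl1, Nkx1-2, Sox3, Gbx2, E2f2, Dlk1, Sox18, Laptm5, Myod1, Neurog2, Igfbp3, Igfbp5 and Actb, while Postn, a fibroblast gene, and Cx3cr1 had one only in Q4 of these 2 fractions. Fibroblast loci held 184 and 162 peaks (percentile 78.6) and mitosis loci 48 and 40 (percentile 59.0). Sites with a 6h MEF peak and no ES cell peak made up 36.9% of Q1 and 43.3% of Q4. The 57762 peaks of Q4 were the fewest, and 88.1% of them overlapped a Q1 peak.

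**Figure D4:**
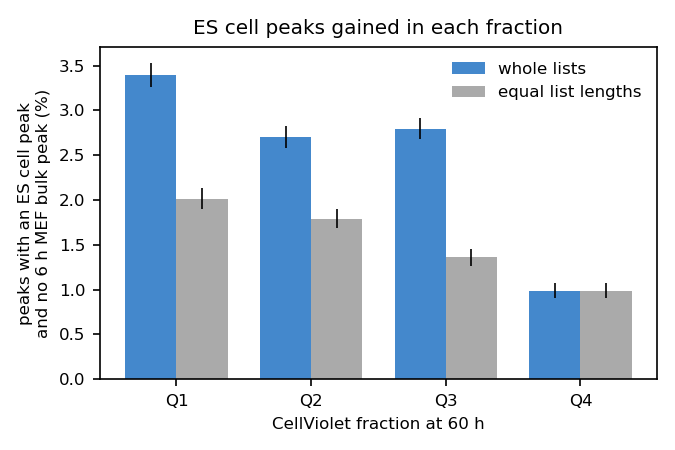
Bars give the percentage of peaks in each sorted fraction that overlap an ES cell bulk peak and no 6h MEF bulk peak, for whole lists and for lists brought to equal length by score, with Wilson 95% intervals covering counting error only. With whole lists Q1 stands at 3.40% and Q4 at 0.989%.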

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

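The tests within strata of bulk score and with the second bulk list were chosen after the odds ratios of loss had been seen.

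The bulk lists of the nascent and mature capture arms differed in opposite directions at different times. By the labels, the bulk samples of the mature arm were collected 2 h after labelling, following a thymidine chase, so the arms need not hold alike material. The mature arm had 25913 more peaks at 6h, a difference of -19400 at 12h and 5508 more at 36h. The difference was not tested, since there is 1 list per arm and time.

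After aphidicolin strong regions fell and weak ones rose. A lower share of fragments in open regions would give a fold set by strength alone; at matched strength, regions at gene ends differed from distal ones by -0.09 (-0.0892 on the log2 scale), just inside the bound of 0.1 set beforehand, with single autosomes from -0.12 to -0.04. Within deciles of strength the difference was negative in 10 of 10 and beyond that bound in 7, from -0.26 in the weakest to -0.04 in the strongest. Strength by CPM alone would not give this, but the bound had been set for the pooled value. Strength was counts per region, not matched on region length or gene density. A lower share of fragments in open regions therefore stays open. Fewer copies of gene-dense, early replicating DNA in blocked cells would shrink the trend within quintiles of gene density. As 0.893 of it was kept, this argues against regional gene density as its cause. Gene density only stands in for replication timing, which can vary within a quintile, so copy number itself stays open. A deeper aphidicolin group, whose lists supplied most regions, is confounded with the treatment and stays open too, as does a biological effect of the block.

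Distal regions in gene-dense megabases fell relative to those in gene-poor ones. The strength trend is not enough to account for this, since 0.849 of the difference was kept at matched strength. The difference then was -0.34 (-0.336 on the log2 scale) and was lower in the gene-dense quintile on 19 of 19 autosomes, from -0.39 to -0.21. This is consistent with a copy-number effect of blocked replication, since gene-dense DNA tends to be copied early, but no replication timing data were used, and a direct effect on accessibility in gene-dense chromatin may give the same.

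Bulk peaks with a mature peak were lost less often. The tests below cover peaks kept in the bulk list at the time of the mature list. In ES cells the strength of the bulk peak at that time is a candidate explanation. Over the kept peaks the odds ratio was 0.312, and within 20 strata of bulk score 0.933. In reprogramming it was 0.0198 and stayed at 0.0900 within strata (0.153 with lists of the mature arm), which argues against single-list strength as the whole cause. A second measurement of the same accessibility could also carry such information: the strongest peaks of the other 12h bulk list, as many as the mature peaks, gave 0.272, between the bounds of 0.135 and 0.3 set beforehand. It therefore stays open how much of the reprogramming result is specific to replicated chromatin.

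The 6 libraries can be split into 10 ways of 3 against 3, too few for a share under 0.05. The real split called 51592 regions and 9082 genes, and the highest other split called 0 of each; 1 of 10 splits reached each count.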

How the results depend on the processing

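Offsets that follow region strength, the restriction to shared regions, counts summed per gene, the early-bulk regions, the 0h mature list, the 20 strata of same-time bulk score, the second bulk list, and the column number as a replicate block were tests chosen after the data were seen.

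The called regions (51592) became 566 when a fold of 1.5 was tested, 31843 with strength offsets and 33626 over regions with a peak in all 6 lists. Leaving out each library gave 33252 to 57589 regions and 6790 to 9748 genes. Genes (9082) became 14 at a fold of 1.5, because most folds were below it. The number of lists called (6) was 4 to 9 with 1 setting changed; over regions within 1 kb of a gene end (9) it was 3 with strength offsets and 0 with an estimated correlation. Among 263 list genes and 82 named regions, no call changed direction in any setting run. Of 3682 comparisons of list genes 317 lost and 110 gained a call, and of 1213 of named regions 79 lost one.

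The count columns share the numbers 1 to 3 between groups, which no source ties to the samples' replicate numbers. With that number as a replicate block 61174 regions, 10558 genes and the same number of lists (6) were called. Deviations from the group means correlated between libraries of the same number at 0.0125 to 0.263 over regions and 0.0421 to 0.469 over genes, and 4 (regions) and 5 (genes) of 6 libraries correlated best with their own number. As 1 of the 3 correlations was below 0.1 in both units, the numbers were not taken as pairs. For peaks per library, sign flips within replicate numbers as a block gave the same difference of 32374.3 (exact p = 0.25, the smallest possible). Score filtering gave 22292.3, and leaving out each sample 28603.3 to 36656.

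The nascent minus bulk gene-end gap was 45.3 (ES cells) and 48.2 points (reprogramming) with higher-scoring peaks, 34.3 in ES cells with 200 bp peaks, and 7.94 and 12.3 at equal lengths. ES cell loss was 39.4% with stricter overlap, 36.3% with higher-scoring peaks, 44.7% with 200 bp peaks and 38.6% at equal lengths; gain was 35.6%, 33.7%, 44.2% and 35.1%. Reprogramming loss was 39.9%, 41.6% and 30.5% for the last 3 settings and 38.9% in the mature arm; gain was 20.8%, 22.7%, 24.5% and 30.2% for the 4 settings and 12.6% in the mature arm. The causes were not tested.

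Odds ratios of gain in ES cells (0.740) were 1.14 at equal lengths, 1.01 over regions of the early bulk list and 0.590 within width strata. Those in reprogramming (3.12) turned to 0.750 in the mature arm and were 0.695 at equal lengths and 1.13 within width strata. They were 8.53 with higher-scoring peaks, 1.32 with 200 bp peaks and 13.1 over early bulk regions. Values at equal lengths are not of gain alone, because the first bulk list was shortened too. In ES cells the main groups differ in make-up, since those without signal are nearly all bulk peaks, and 0.740 became 1.01 when both were. Other causes were not tested. Odds ratios of loss stayed below 1 in every setting run. Within score strata they were 0.316 in ES cells and 0.0315 in reprogramming. Within same-time strata, over peaks kept in the bulk list of that time, they were 0.933 and 0.0900. In such strata the mature arm gave 0.153 and the second bulk list 0.272. The 0h mature list gave 0.283 in ES cells (0.876 within strata of the first peak's score). The Q1 to Q4 ratio (3.44) was 2.62 with higher-scoring peaks, 1.37 with 200 bp peaks and 2.04 at equal lengths.

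GC offsets, alone or with the block, and motif sets were not run, because no genome sequence was given, and a pseudocount does not apply to counts. The simulation, with 50 changed features at each fold, recovered 6% of regions at the smallest simulated fold. So few changes make the adjusted threshold stricter than in the real data, where 51592 regions were called. These rates therefore do not give the sensitivity here, though small changes of single regions can be missed.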

Other observations

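The list of serum response factor genes and the test of regions gained at ES cell sites were chosen after related results had been seen, the first after Actb, Actg1 and Zyx stood out and before its other members were looked at.

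Among single loci, the changes in bulk peak number from 0h to 48h of EpiLC conversion were largest at Tenm4 (falling) and Gpc5 (rising). Tenm4 went from 120 to 66 peaks, Tenm3 from 117 to 66 and Tmem132d from 66 to 22, while Gpc5 went from 12 to 53, Anks1b from 27 to 62 and Trio from 31 to 63. In reprogramming Macrod2 went from 135 to 75 between 6h and 36h, Rbms3 from 128 to 74 and Tmem164 from 21 to 29. In the ES cell mature lists naive loci went from 118 to 67 peaks between 0h and 48h and formative loci from 70 to 114 (percentile 99.5), but muscle and neural loci also went from 22 to 41 (percentile 98.7), endothelial loci from 24 to 30 (97.3) and epithelial loci from 59 to 85 (95.8).

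Loss of accessibility at actin genes after aphidicolin may extend to other genes regulated by serum response factor. Of 22 such genes 20 fell and 1, Filip1l, rose, with Flna at -0.47, Tgfb1i1 at -0.44, Myl9 at -0.43 and Acta2 at -0.38. With strength offsets the median was -0.17, at percentile 0 of 10000 random lists matched on counts, and 17 fell and 1 rose. The random lists were not matched on gene density, and the ubiquitous list fell as well (median -0.13 with the same offsets), so a wider loss at active genes is not excluded.

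Regions gained in reprogramming at ES cell sites had lower folds after aphidicolin than other regions of their strength (median difference -0.18). This appears only once strength is adjusted for: the median fold was 0.00 with TMM (615 higher, 614 lower) and -0.19 (-0.188) with strength offsets, which restate the matching and test nothing further. Regional gene density may contribute: matched on it as well, the median was -0.14 (-0.139), below -0.1 on 16 of 19 autosomes where 17 had been required beforehand, which leaves the question open.

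Among regions of the 9h bulk list outside the 0h list, no excess of 48h bulk peaks was seen at those with replicated chromatin signal: within deciles of the 9h bulk score the odds ratio was 0.715. Over regions of the merged early lists at equal list lengths it was 1.14. That set also holds weaker 0h bulk peaks, because the 0h list was shortened, so it cannot show whether a small excess in gain exists.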
